A study of Mus musculus with 8 samples.

How the data were processed

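The deposited data were 4 expression libraries and 4 TCR libraries, made with 10x Genomics 5′ gene expression and V(D)J chemistry per the labels' protocols. Each expression library is a matrix of raw UMI counts per gene and barcode, made with Cell Ranger 4.0.0 (experiment 1, 31053 genes) and 6.1.2 (experiment 2, 32285 genes) per the file headers, on GRCm38 per the submitters' processing notes. The deposited TCR tables list assembled contigs per barcode with UMI counts per contig, by Cell Ranger per the submitters' processing notes, and their version is not given in the sources used here. The matrices hold only barcodes kept upstream, and how these were chosen is not given in the sources used here. Because the experiments differ in dose, timing, cell isolation and Cell Ranger version, expression, shares and repertoires were compared within an experiment only, and shared clonotypes were also counted across experiments.

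Cells with at least 500 detected genes and under 10% mitochondrial UMIs were kept. Scrublet (scanpy 1.11.5, expected rate 6%) marked 0 cells in all libraries, with thresholds from 0.579 to 0.690; it has not worked here, and no doublets were removed. Cells of both libraries of an experiment were clustered together on 2000 variable genes without TCR, immunoglobulin, mitochondrial and ribosomal genes, with 30 principal components, 20 neighbours and the Leiden method (leidenalg 0.10.2, resolution 1). This gave 21 clusters in experiment 1 and 23 in experiment 2.

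The class compared was settled after the clusters had been seen. A cluster entered it if the summed CPM of its T cell markers and of Cd8a and Cd8b1 each reached 40% of the highest cluster, if markers of macrophages, dendritic cells, neutrophils, B cells and fibroblasts stayed under 10% of their highest cluster, if Cd8a plus Cd8b1 exceeded Cd4, and if its cells' median UMI count was at least 1/3 of their library's. The name CD8 T-like, fixed before the data were examined, was not used, because a check of marker genes failed: a cluster should not have more markers of another cell type than of T cells among its top 10 genes by fold. The check was run against 4 comparators, and each left at least 1 failing cluster in experiment 2. Each failure was 1 gene, named in brackets below, against 0 T cell markers, so the check alone does not settle what these cells are. Against all other cells, cluster 7 of experiment 1 (Areg) and cluster 6 of experiment 2 (Itgax) failed. Against the clusters outside the class, cluster 4 of experiment 2 (Eomes) failed. Against non-T clusters, clusters 0, 10, 12 and 18 of experiment 1 (Eomes) and cluster 1 of experiment 2 (Ccr7) failed, and with mixed clusters added to these, clusters 0, 3, 12 and 18 of experiment 1 and cluster 4 of experiment 2 (Eomes). The set is therefore called the Cd8-high clusters, numbers 0, 1, 2, 3, 7, 8, 9, 10, 12, 15 and 18 in experiment 1 and 0, 1, 4, 5, 6, 7, 8, 9, 11, 12, 13 and 17 in experiment 2.

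The thresholds kept other cells out, in the order buffer, rhIL-7-hyFc 10 mg/kg, rhIL-7-hyFc 1.25 mg/kg, combination. Clusters with T cell RNA and low Cd8, left unnamed, held 8.28%, 4.97%, 3.04% and 2.76% of cells. Clusters with both T cell and myeloid RNA held 4.68%, 0.871%, 37.2% and 8.44%. Non-T clusters held 14.3%, 4.45%, 1.83% and 0.159%, and clusters of low UMI counts, left unnamed, 14.2%, 2.68%, 1.76% and 2.42%.

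UMI counts were summed per library over these clusters (33344367 and 57766124 UMIs in experiment 1, 45510092 and 74012980 in experiment 2) and expressed as CPM. Log2 ratios were taken on CPM + 1, and folds as ratios of CPM with exact intervals from the conditional binomial distribution; CPM have exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95%. There were 28 gene lists, and members with at least 5 CPM in 1 of the 2 libraries counted as measured. A list's median has a counting interval from 500 Poisson draws and a percentile among 10000 random lists of the same size matched in 20 expression bins, which describes these libraries and is not a test.

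The named genes follow a rule: among genes with at least 50 CPM in 1 library, without TCR, immunoglobulin, mitochondrial, ribosomal, haemoglobin and unnamed genes, the 10 highest and the 10 lowest log2 ratios; from each list the 3 members with the largest absolute log2 ratio; and always Pdcd1, Entpd1, Havcr2, Tox, Tcf7, Il7r, Gzmb, Ifng and Mki67. A gene that the rule also takes is not reported here. The gene lists, this rule, the comparisons and the alternatives were set before the data were examined, except those added later. These left out clusters that failed the marker check under each of its 4 versions, left out cells with more than 1 beta chain and top Scrublet scores, added the clusters of low UMI counts, or took the share of cells under looser filters. All 153 identifiers of named genes matched the GENCODE M21 annotation of GRCm38, from which coordinates were taken.

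To compare shares of cells with a UMI, cells were thinned at random to the lower of the 2 libraries' 10th percentiles, rounded down to 100 UMIs, and shallower cells were left out. A clonotype is the set of productive alpha and beta CDR3 nucleotide sequences of a cell, for cells with both chains and 1 beta chain. Repertoires were compared at equal cell numbers over 1000 random draws. Expanded clonotypes have at least 5 cells in the Cd8-high clusters of a library. Clone sizes were counted over all such cells of a library, not at equal cell numbers. The classes with and without a Pdcd1 or Entpd1 UMI are ranges set by 2 genes, not cell types, and a limit of 2 UMIs in place of 1 was among the alternatives.

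The ratio and list steps were tested on simulated counts with 200 genes changed. Both libraries were Poisson draws from the summed profile of the control library, the model that the intervals assume. Coverage near 95% was thus set by the design, and clustering of UMIs within cells or clonotypes was not simulated. For the first comparison (8472 genes) 95.1% of intervals held the true ratio over all genes and 94.5% over changed genes, and for the second (8703 genes) 95.1% and 96.0%. The sign was right in 100% of genes at each of the folds 1.5, 2 and 4 in both. A list of raised genes had percentile 100 in both, and a list of unchanged genes 68.3 and 10.7. Alternative scalings used edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (size factors) for their factors only, in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Other alternatives changed the cell filters, the gate, the clustering and the weighting of cells and clonotypes. The count minimum, the pseudocount (0.1 for 1) and the clone size limit were changed too. The gate on UMIs took cells with a Cd8a or Cd8b1 UMI, a Cd3d, Cd3e or Cd3g UMI and no Cd4 UMI. It was not limited to the Cd8-high clusters, so cells with both T cell and myeloid RNA could enter it.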

Results

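The series profiled CD8 T cells isolated from MC38 tumours, a mouse colon carcinoma line grown in C57BL/6 mice, by droplet single-cell 5′ RNA sequencing paired with sequencing of T cell receptors (TCRs). There were 2 experiments. In experiment 1 mice received buffer or rhIL-7-hyFc, a long-acting interleukin-7 fused to an Fc part, at 10 mg/kg under the skin, and tumours were collected 7 days later. In experiment 2 mice received rhIL-7-hyFc at 1.25 mg/kg, alone or with a T cell engager (TCE), a bispecific antibody against mouse PD-L1 and CD3ε, given intravenously from day 3 after rhIL-7-hyFc. The labels state a daily schedule with the number 3, which can mean 3 doses on successive days or 3 doses per day. Tumours of both groups of experiment 2 were taken 24 hours after the last treatment. The time from rhIL-7-hyFc to collection was not recorded here for these groups, so whether it was the same in both was not checked. CD8 T cells were taken with magnetic beads in experiment 1 and by flow sorting of viable CD45+ TCRβ+ CD8α+ cells in experiment 2. Each group was 1 expression library and 1 TCR library, and how many mice were pooled in each is not given in the sources used here. With 1 library per group there is no replicate check and no test. All intervals are 95% intervals that cover counting error only, not the spread between mice.

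The expression libraries held 5589 barcodes (buffer), 6361 (rhIL-7-hyFc 10 mg/kg), 12560 (rhIL-7-hyFc 1.25 mg/kg) and 11501 (rhIL-7-hyFc plus TCE). Their total counts were 47308214, 65036440, 118191371 and 92863323 unique molecular identifiers (UMIs). After the cell filters 4697, 5973, 12307 and 11301 cells remained, with medians of 7945, 9696, 6698 and 6625 UMIs per cell. Values below come from clusters with high Cd8a and Cd8b1, called the Cd8-high clusters. They held 2751 cells (58.6%, interval 57.1 to 60.0) with buffer, 5198 cells (87.0%, 86.1 to 87.9) with rhIL-7-hyFc 10 mg/kg, 6919 cells (56.2%, 55.3 to 57.1) with rhIL-7-hyFc 1.25 mg/kg and 9743 cells (86.2%, 85.6 to 86.8) with the combination. The bead selection and the sort set these shares in part. In experiment 2 they moved to 30.5% and 70.0% with coarser clusters.

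The first comparison asked how rhIL-7-hyFc alone altered CD8 T cells in the tumour. In the rhIL-7-hyFc library, genes of naive and memory T cells were higher and genes of exhausted T cells were lower than in the buffer library. Tcf7, which encodes the transcription factor TCF-1 of naive and stem-like T cells, was 4.80-fold higher (interval 4.49 to 5.12). Havcr2, which encodes the inhibitory receptor TIM-3, was 6.25-fold lower (5.87 to 6.67), and Pdcd1, which encodes PD-1, was 4.05-fold lower (3.94 to 4.15). Among genes with at least 50 CPM (counts scaled to the same total in each library) in 1 library, the widest gaps in either direction were in Gzmm, a granzyme gene that went from 8.79 to 143 CPM, 16.2-fold higher (14.4 to 18.3), and in Il1r2, 8.42-fold lower (7.82 to 9.08).

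Of the 21 measured genes of the naive and memory list, 15 were at least 1.5-fold higher and 1 was at least 1.5-fold lower. The list median was a log2 ratio of 1.22 (interval 1.12 to 1.26), above all of 10000 random lists matched on expression (percentile 100). It was 0.39 when each clonotype counted once and 0.77 without cells that had an Mki67 or Top2a UMI. Under a gate on Cd8, Cd3 and Cd4 UMIs, applied to cells of all clusters, it was 0.75. S1pr1, the receptor that guides T cells out of tissues, was 4.92-fold higher (4.55 to 5.32). Of 20 measured exhaustion genes 17 were at least 1.5-fold lower, with a median of −1.82 (−1.89 to −1.74; percentile 0). Ctla4 was 4.85-fold lower (4.68 to 5.02), Tox 3.94-fold lower (3.68 to 4.22), Ccl3 5.29-fold lower (5.05 to 5.54) and Entpd1, which encodes CD39, 3.10-fold lower (2.93 to 3.27). The median over all 8741 genes was −0.15. Scaling by TMM factors moved the median of all genes by 0.21, and with it the naive and memory list stood at 1.43 and the exhaustion list at −1.62.

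Cytotoxicity genes had a median of −0.95 (−0.96 to −0.94), with 12 of 19 lower and 1 higher, and −0.63 when each clonotype counted once. Prf1 (perforin) was 5.60-fold lower (5.48 to 5.74), Gzmk 6.07-fold lower (5.70 to 6.46) and Gzmb 1.93-fold lower (1.92 to 1.94), while Gzmm was the member that was higher. Among the genes of DNA replication, 37 of 43 were lower (median −0.93), and among the genes of G2 and mitosis 42 of 51 (median −0.99). Mki67 was 1.87-fold lower (1.77 to 1.97). Glycolysis genes had a median of −0.84 with 15 of 19 lower, among them Bnip3 (5.27-fold, 4.92 to 5.65) and Slc2a3 (3.70-fold, 3.45 to 3.97). Medians were also negative for tissue residency (−0.84, with 9 of 16 lower and 1 higher, Cxcr6 3.73-fold lower) and effector differentiation (−0.77, 13 of 21 lower and 2 higher, Zeb2 4.78-fold lower). The same held for NK-type receptors (−0.76, 7 of 13 lower and 2 higher, Klrk1 3.74-fold lower) and cholesterol synthesis (−0.74, 12 of 18 lower and 0 higher, Sqle 2.68-fold lower). Cytokines and chemokines went both ways, 8 lower and 4 higher of 16 (median −0.51). Ifng was 3.75-fold lower. Il2 was at 0.210 and 5.18 CPM, but 1 cell of cluster 18 held 267 of its 299 UMIs with rhIL-7-hyFc, so its counting interval does not apply, and its log2 ratio of 2.35 turned to −0.13 and −0.14 without sets of clusters that include cluster 18. The NK-type receptor median was 0.15 without the cells with an Mki67 or Top2a UMI.

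Interferon-induced genes were higher. Of 33 type I interferon response genes 21 were at least 1.5-fold higher and 0 lower (median 0.83, 0.78 to 0.86; percentile 100), with Oasl2 4.42-fold higher (4.16 to 4.69) and Ifit3b 3.05-fold higher (2.87 to 3.24). The interferon gamma response list had a median of 0.50, with 13 of 30 higher and 1 lower, Serpina3g (3.38-fold lower, 3.23 to 3.53). Genes of the IL-7 and STAT5 response went both ways, 6 higher and 5 lower of 19 (median 0.34). Socs3, a feedback inhibitor of cytokine signals, was 2.96-fold higher (2.85 to 3.08) and Ptger2 was 5.21-fold lower (4.26 to 6.42). The list median was −0.091 when each clonotype counted once. Il7r itself was 1.20-fold higher (1.16 to 1.25). Ribosomal protein genes had a median of 0.35, with 5 of 48 higher and 0 lower.

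The lists for early genes of TCR signals (−0.19), AP-1 and heat shock genes (−0.17), oxidative phosphorylation (−0.12), ribosome biogenesis (−0.23), apoptosis and survival (−0.18) and transcription factors of CD8 T cells (−0.14) had medians within the central 95% of random lists, and under TMM scaling all but ribosome biogenesis turned to between 0.023 and 0.089. Of the 20 early genes of TCR signals 9 were at least 1.5-fold lower and 1 higher, among them Tnfrsf4 (5.09-fold lower), Tnfrsf9 (3.87-fold lower) and Irf8 (3.45-fold lower). Of the 20 AP-1 and heat shock genes 6 were lower and 2 higher, with Hspa1a 6.72-fold and Atf3 5.44-fold lower. Transcription factors went both ways (9 higher and 11 lower of 29), as did apoptosis and survival genes (4 higher and 6 lower of 21). In oxidative phosphorylation 0 of 32 genes reached 1.5-fold, and in ribosome biogenesis 1 of 30 was lower. CD3 and TCR signalling (0.11), cytokine receptors (0.16) and chemokine receptors, integrins and egress (0.092) lay just above it. Cytokine receptors turned to −0.0043 when at least 20 CPM were required, and chemokine receptors, integrins and egress to −0.028 when each clonotype counted once and −0.0014 as a mean over cells. Markers of other cells also differed. Macrophage and monocyte markers had a median of −1.93, with 10 of 12 lower, beside the lower lists named above (Cd74 from 87.2 to 16.7 CPM). The CD4 T cell list had a median of −1.80 over 3 genes, Ikzf2, Izumo1r and Tnfrsf4. Cd4, Cd40lg and Foxp3 were not among its measured genes, and Tnfrsf4 is also an early gene of TCR signals. Areg was the only measured gene of the tumour cell list (58.5 to 9.69 CPM). Of 3 B cell markers Igkc was lower (6.09 to 0.364 CPM) and Ighm higher (27.8 to 105 CPM). The B cell list median was 1.44, and −0.18 under the gate on UMIs.

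**Figure D1:**
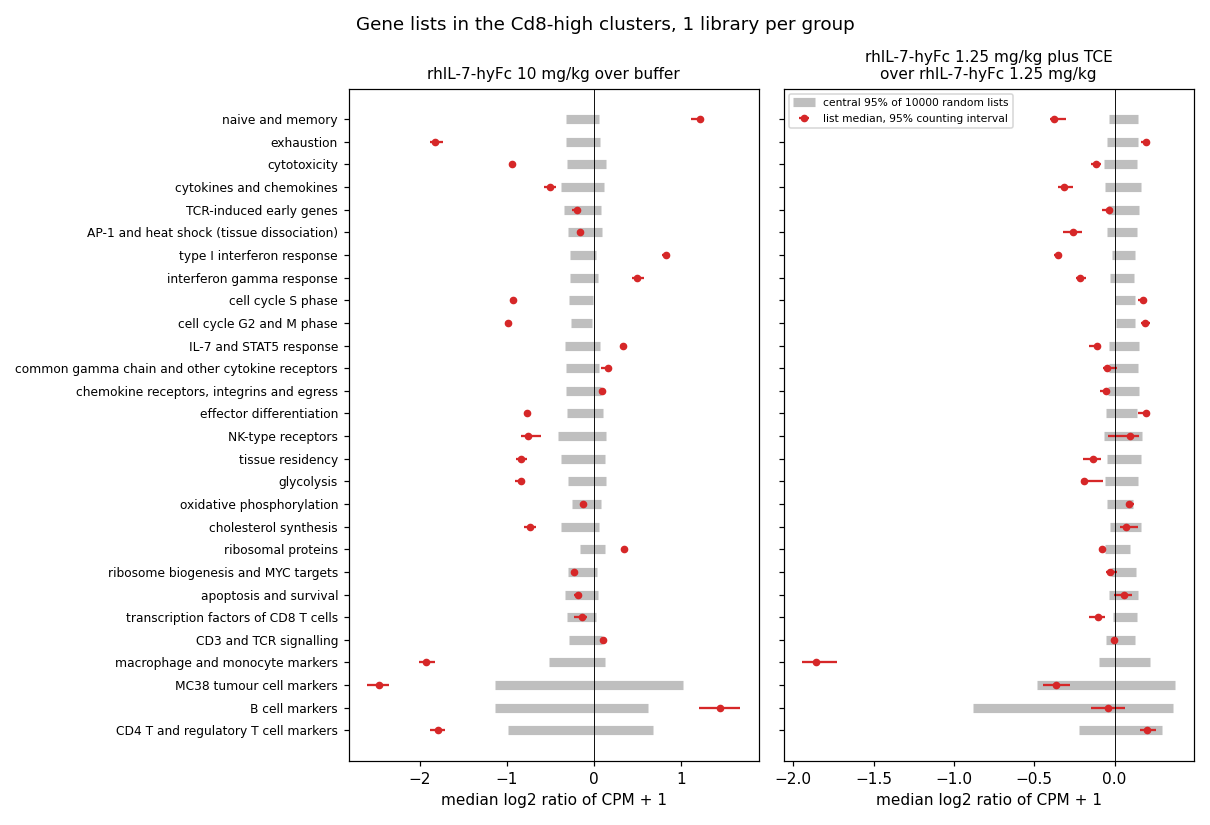
Median log2 ratio of CPM + 1 (horizontal axis) for each gene list (vertical axis) in the Cd8-high clusters, treated over control library, for experiment 1 (left) and experiment 2 (right), as points with 95% counting intervals over grey bars for the central 95% of 10000 random lists. The naive and memory list lies at 1.22 on the left and −0.38 on the right, and the exhaustion list at −1.82 and 0.20.

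Different clusters held most cells of each library. With buffer these were cluster 1 (958 cells, against 386 with rhIL-7-hyFc), cluster 7 (431 against 144), cluster 8 (350 against 160) and cluster 9 (341 against 84), and with rhIL-7-hyFc cluster 0 (2038 cells, against 87 with buffer), cluster 2 (1054 against 180) and cluster 3 (920 against 130). When each clonotype counted once, several values moved by over 1.5 times. The log2 ratios were 0.63 for Tcf7 (2.22 over all cells), 0.62 for S1pr1 (2.25), 2.55 for Gzmm (3.88), −2.77 for Pdcd1 (−2.01) and −3.33 for Havcr2 (−2.59). The medians were 0.44 for the type I interferon response, 0.27 for interferon gamma, −0.39 for cholesterol synthesis, −1.20 for cytokines and chemokines and 0.15 for ribosomal proteins. NK-type receptors stood at −0.25 after thinning, and the IL-7 and STAT5 response at 0.062 under the gate on UMIs. Clusters that failed a version of the marker check were left out in turn. Clusters 0 and 3 among them held mostly cells of the rhIL-7-hyFc library, so leaving them out removes much of that library. Without clusters 0, 3, 12 and 18 the exhaustion median was −1.01, cytotoxicity −0.47, tissue residency −0.36, cytokines and chemokines −0.21, S phase −0.28, G2 and M −0.10, the type I interferon response 0.23, interferon gamma 0.084 and the IL-7 and STAT5 response 0.10. Effector differentiation genes were then at −0.49, CD4 T cell markers at −0.93, cytokine receptors at 0.034, CD3 and TCR signalling at 0.020 and chemokine receptors, integrins and egress at −0.024. The log2 ratios were −0.99 for Pdcd1, −1.59 for Havcr2 and 0.046 for Mki67. Without clusters 0, 10, 12 and 18 the type I interferon median was 0.46 and interferon gamma 0.21. Single cells were next compared after each was thinned to 4400 UMIs, which left out 267 cells with buffer and 122 with rhIL-7-hyFc. A Pdcd1 UMI was found in 70.7% of cells with buffer (68.9 to 72.5; unthinned 77.7%) and in 14.4% with rhIL-7-hyFc (13.4 to 15.4; unthinned 17.5%). Non-T cells of the same libraries gave 17.1% and 4.07%. Their median depths were 9934 and 14261 UMIs, against 10170 and 9878 in the Cd8-high clusters. A Tcf7 UMI was found in 12.6% and 43.8% of cells (unthinned 18.4% and 64.5%; non-T 6.65% and 7.72%). Cells with neither a Pdcd1 nor an Entpd1 UMI, a pattern used to describe bystander cells, made up 24.0% (22.3 to 25.7) with buffer and 79.4% (78.3 to 80.5) with rhIL-7-hyFc, and 18.9% and 69.8% unthinned (non-T 55.6% and 66.7%). When at least 2 UMIs were needed these shares were 41.7% and 88.6%. With buffer the Entpd1 share (32.2%, 30.3 to 34.0) was not separated from that in non-T cells (30.9%, 27.1 to 35.0), nor was Il7r (37.2% against 37.4%). With rhIL-7-hyFc the shares for Entpd1 (10.1% against 30.5%) and Havcr2 (4.35% against 22.0%) lay below those in non-T cells and are not read as expression or as a difference, and the Mki67 share (7.21%) was not separated from theirs (4.88%). The share with neither gene rests in part on Entpd1. Non-T clusters included clusters led by macrophage genes (Lyz2 and C1qa in cluster 5) and dendritic cell genes (Ccl22 and Fscn1 in cluster 13). Their own expression could not be told apart from free RNA, so their shares do not measure free RNA alone. The CPM ratios given above were not corrected for background.

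The TCR repertoire was less clonal in the rhIL-7-hyFc library. Repertoire values can also depend on how many mice were pooled per library, which is not given. Drawing equal cell numbers does not adjust for this. Among 2190 cells drawn from each library, buffer gave 777 clonotypes and rhIL-7-hyFc 2020 (central 95% of 1000 draws 2001 to 2041). Clonotypes of at least 2 cells held 71.3% of cells with buffer and 10.7% with rhIL-7-hyFc (9.50 to 11.7), and the 10 largest held 33.7% and 3.68%. The Gini-Simpson index was 0.984 and 0.99980.

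Expression was also compared by clone size, without a test of the difference between classes. Clone sizes were counted in 2190 cells with buffer and 4364 with rhIL-7-hyFc, so a class can mean different clone frequencies in each library. In each library, cells of clonotypes with at least 5 cells had higher exhaustion genes than cells of clonotypes seen once, by a median log2 ratio of 1.33 with buffer and 3.15 with rhIL-7-hyFc. Between the libraries, exhaustion genes had a median of −0.10 (interval −0.16 to −0.04) within the expanded clonotypes (1330 and 343 cells) and of −1.90 (−2.15 to −1.55) within clonotypes seen once (629 and 3832 cells). Pdcd1 was at 694 and 705 CPM within expanded clonotypes and at 219 and 27.6 CPM within those seen once. G2 and mitosis genes had medians of −0.020 and −0.94 in these classes, and Mki67 was at 81.1 and 79.6 CPM in the first and at 65.7 and 32.1 CPM in the second. Type I interferon genes were higher in both, with medians of 0.62 and 0.53. Within cells with neither Pdcd1 nor Entpd1 (519 and 3626 cells) the naive and memory median was 0.30 and the exhaustion median −1.42, and within cells with a UMI of either gene (2232 and 1572 cells) they were 1.01 and −0.73. Pdcd1 and Entpd1 are themselves members of the exhaustion list, so the exhaustion medians by class are in part set by the cut. With classes from thinned UMIs the naive and memory median in cells with neither gene was 0.46, and the exhaustion medians were −2.32 and −0.46.

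**Figure D2:**
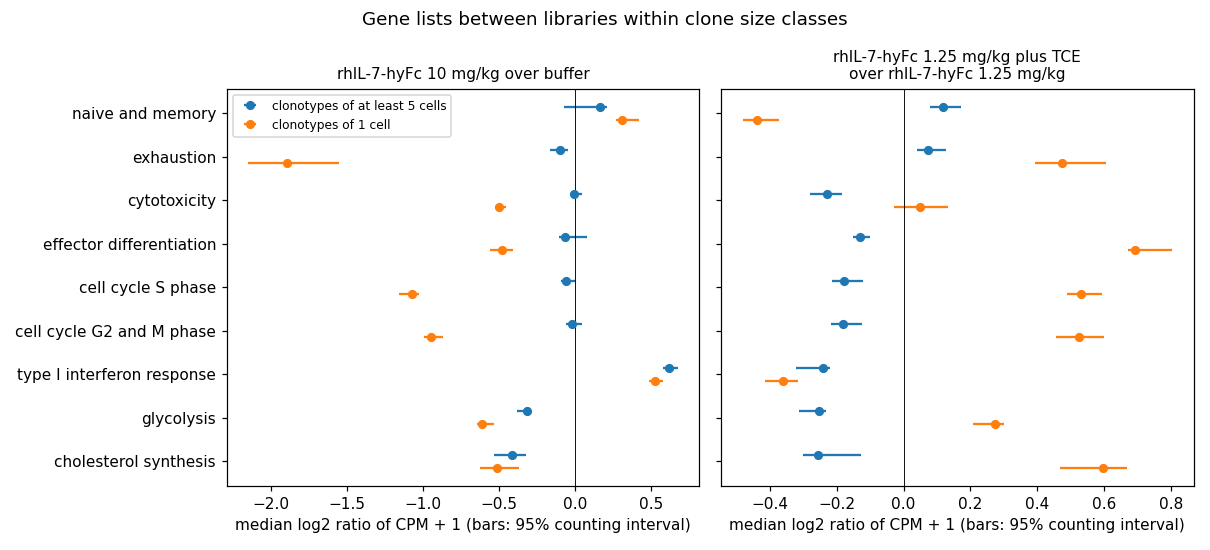
Median log2 ratio of CPM + 1 (horizontal axis), treated over control, for 9 gene lists (vertical axis) in cells of clonotypes with at least 5 cells (blue) and of clonotypes with 1 cell (orange); bars are 95% counting intervals. In experiment 1 (left) the exhaustion list lies at −0.10 and −1.90, and in experiment 2 (right) the G2 and M list lies at −0.18 and 0.53.

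The second comparison asked what the TCE added to rhIL-7-hyFc. Gzma, which encodes granzyme A, went from 258 CPM (interval 253 to 263) with rhIL-7-hyFc to 3100 CPM (3087 to 3112) with the combination, 12.0-fold higher (11.8 to 12.2). Gzmk was 4.39-fold higher (4.17 to 4.62), the terminal effector marker Klrg1 4.76-fold higher (4.09 to 5.57) and the chemokine gene Ccl5 2.53-fold higher (2.51 to 2.55). Tcf7 was 2.15-fold lower (2.06 to 2.23) and Dapl1 2.80-fold lower (2.62 to 2.99).

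The further genes among the 10 with the highest ratios were Wdr95 (3.62-fold), Ccl1 (2.69-fold), the integrin gene Itga4 (2.23-fold), Ass1 (1.97-fold), Nrgn (1.83-fold), Rasgrp2 (1.80-fold) and Ctla4 (1.76-fold). Ass1 and Anxa1 turned to log2 ratios of −0.52 and −0.66 under the gate on Cd8, Cd3 and Cd4 UMIs, taken over all clusters. Among the 10 with the lowest ratios were Cd74 (3.37-fold lower), Fcer1g (2.17-fold), Cxcl10 (2.09-fold), Oasl2 (2.10-fold), Xcl1 (1.92-fold) and H2-Q7 (1.90-fold). Cd74 and Fcer1g are also members of the macrophage and monocyte list. Clusters with both T cell and myeloid RNA held 37.2% of cells with rhIL-7-hyFc and 8.44% with the combination. The ratios were not corrected for background, so a difference in free myeloid RNA cannot be told apart from one in CD8 T cells.

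The median over all 8922 genes was 0.065. Naive and memory genes had a median of −0.38 (−0.40 to −0.30), with 5 of 20 at least 1.5-fold lower and 0 higher. Under the gate on UMIs it was 0.043. The gate could admit cells of clusters with both T cell and myeloid RNA, which held 37.2% (rhIL-7-hyFc) and 8.44% (combination) of cells. How much this moved the median was not tested. Exhaustion genes had a median of 0.20 (0.17 to 0.22), with 3 of 20 higher, Ctla4, Tigit (1.69-fold) and Nrn1 (1.58-fold). It was 0.59 when each clonotype counted once and 0.33 after thinning. Pdcd1 was 1.15-fold higher (1.13 to 1.16) and Havcr2 1.37-fold higher (1.31 to 1.43). Cytotoxicity genes had a median of −0.11 with 2 of 19 higher (Gzma and Gzmk) and 2 lower, among them Gzmm (2.78-fold lower); the median was 0.016 after thinning, 0.043 when each clonotype counted once and 0.0020 without cells that had an Mki67 or Top2a UMI.

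Effector differentiation genes had a median of 0.19 with 3 of 20 higher (Gzma, Klrg1 and Anxa1) and 1 lower. The medians of the S phase list (0.17) and the G2 and M list (0.19) had percentiles of 99.98 and 100, with no gene reaching 1.5-fold, and Mki67 was 1.17-fold higher (1.13 to 1.22). The type I interferon list had a median of −0.35, with 5 of 32 genes at least 1.5-fold lower and 0 higher (Usp18 1.64-fold lower, Bst2 1.63-fold lower). The interferon gamma list had a median of −0.21, with 3 of 30 lower and 0 higher (Tgtp2 1.76-fold lower). Medians were also negative for cytokines and chemokines (−0.32, with 4 of 14 lower and 2 higher), AP-1 and heat shock genes (−0.26, 5 of 20 lower), glycolysis (−0.19, 0 of 19), tissue residency (−0.14, 4 of 16), the IL-7 and STAT5 response (−0.11, 3 of 20), transcription factors of CD8 T cells (−0.10, 3 of 29) and ribosomal proteins (−0.077, 4 of 48). Counting each clonotype once turned glycolysis to 0.20 and residency to 0.013, and the gate on UMIs turned ribosomal proteins to 0.093. Chemokine receptors, integrins and egress (−0.055), cytokine receptors (−0.047) and ribosome biogenesis (−0.025) lay below the central 95% of random lists, with percentiles of 1.28, 1.43 and 1.89, and the first and the last turned to 0.0091 and 0.089 under the gate. Ribosome biogenesis was also at 0.0052 after thinning and 0.051 without cluster 6. Early genes of TCR signals (−0.032), NK-type receptors (0.095), oxidative phosphorylation (0.087), cholesterol synthesis (0.074), apoptosis and survival (0.058) and CD3 and TCR signalling (−0.0046) lay within it, and all of these but oxidative phosphorylation changed sign under at least 1 alternative. Macrophage and monocyte markers were lower, with a median of −1.86 and 8 of 10 lower (Lyz2 from 16.9 to 2.18 CPM), beside the negative medians of the naive and interferon lists. The medians were −0.36 for Areg, the measured tumour cell marker, −0.044 for B cell markers and 0.20 for the CD4 T cell list. The latter again rests on Ikzf2, Izumo1r and Tnfrsf4. B cell markers turned to between 0.025 and 0.23 under the gate, with each clonotype once and without cluster 4 or cluster 1, and CD4 T cell markers to −0.085 with each clonotype once and at a CPM of at least 20.

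Cluster 6 (80 cells with rhIL-7-hyFc and 1390 with the combination), cluster 11 (160 and 688) and cluster 0 (1082 and 1994) held more of the combination library, and cluster 4 (1320 and 596) and cluster 1 (1809 and 1220) more of the rhIL-7-hyFc library. When each clonotype counted once, the log2 ratios were 4.44 for Gzma (3.58 over all cells), 2.74 for Gzmk (2.10), 1.82 for Ctla4 (0.81) and 1.47 for Havcr2 (0.45). The medians were then 0.56 for effector differentiation, 0.52 for S phase, 0.47 for G2 and M and −0.11 for cytokines and chemokines. Under the gate on UMIs they were 0.054 for effector differentiation, −0.63 for the type I interferon response and −0.39 for tissue residency. Leaving out clusters that failed a version of the marker check moved several medians. Gzma had a log2 ratio of 2.96 without cluster 6, and Gzmm of −0.43 without cluster 1. The naive and memory median was −0.48 without cluster 6, −0.21 without cluster 4 and −0.14 without cluster 1, and the exhaustion median was 0.34, 0.076 and 0.053. S phase genes stood at 0.30, 0.045 and 0.034, G2 and M genes at 0.36, 0.082 and 0.060, and effector differentiation genes at 0.19, 0.089 and 0.099. The type I interferon median was −0.20 and the interferon gamma median −0.082 without cluster 4. Pdcd1 had log2 ratios of 0.35, 0.037 and 0.012. Cells were thinned to 3400 UMIs, which left out 650 and 508 cells. A Pdcd1 UMI was found in 45.8% (44.6 to 47.0; unthinned 49.1%) and 56.1% (55.0 to 57.1; unthinned 63.0%) of cells, against 11.3% and 5.56% in non-T cells. A Tcf7 UMI was found in 30.4% and 14.7% (unthinned 38.9% and 20.8%; non-T 3.30% and 0%). Cells with neither a Pdcd1 nor an Entpd1 UMI made up 51.7% (50.4 to 52.9) and 37.3% (36.3 to 38.3), and 48.3% and 28.2% unthinned (non-T 77.4% and 88.9%). Median depths in the Cd8-high clusters were 5542 and 6536 UMIs, and in non-T cells 7289 and 6523 UMIs. Before thinning, non-T cells were of clusters 18 and 22 with rhIL-7-hyFc (197 and 28 cells) and of cluster 18 alone with the combination. Genes that led cluster 18 include Siglech, Klk1 and Ccr9, which are markers of plasmacytoid dendritic cells. The combination library had 18 non-T cells, so that the exact interval of a share of 0 in them reaches 18.5%. In that library the shares for Tcf7 (14.7%), Havcr2 (18.4%), Entpd1 (20.3%), Ifng (19.5%), Il7r (45.7%) and Mki67 (11.4%) were not separated from background at this depth. With rhIL-7-hyFc the Entpd1 share (12.8%) was not separated from that in non-T cells (11.3%), and the Il7r share (48.3%) lay below theirs (59.0%) and is not read as expression or as a difference. The share with neither gene rests in part on Entpd1 here too, and own expression in non-T cells could again not be told apart from free RNA.

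**Figure D3:**
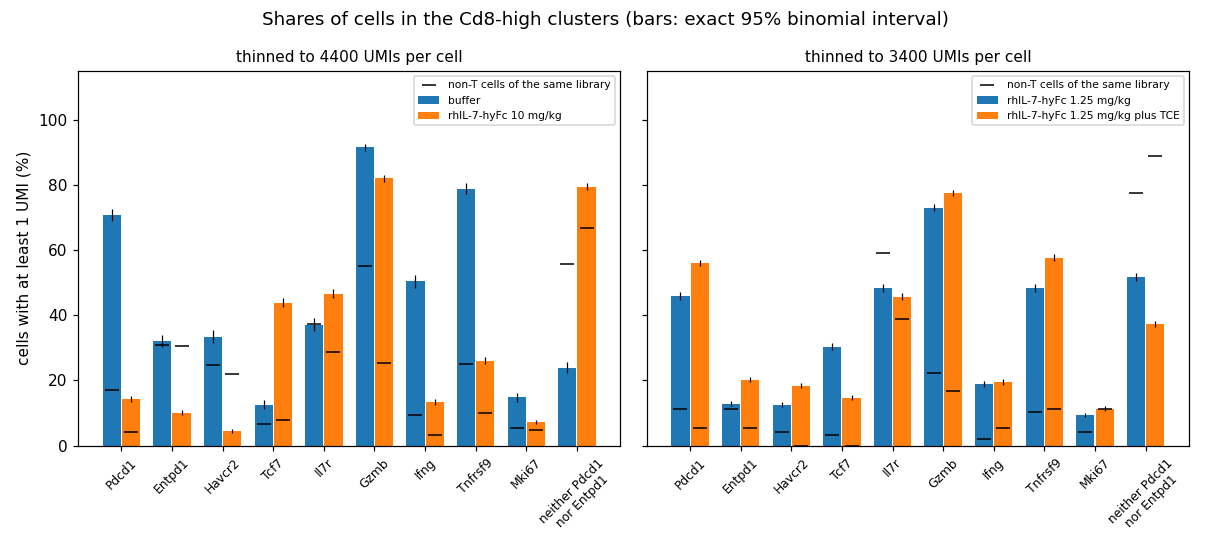
Share of cells in the Cd8-high clusters with at least 1 UMI of each gene, or with neither Pdcd1 nor Entpd1 (vertical axis, percent), after thinning to 4400 UMIs (experiment 1, left) and 3400 UMIs (experiment 2, right), with exact 95% binomial intervals and black dashes for non-T cells of the same library, 18 cells for the combination. Cells with neither gene made up 24.0% and 79.4% on the left and 51.7% and 37.3% on the right.

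Among 4538 cells drawn from each TCR library there were 2833 clonotypes with rhIL-7-hyFc and 2520 with the combination (2486 to 2557), an order that turned when all cells were used (2833 and 3409). Clonotypes of at least 2 cells held 42.7% and 49.9% (49.0 to 50.7) of cells, the 10 largest held 12.5% and 19.7%, and the Gini-Simpson index was 0.997 and 0.992. Here too the number of mice pooled per library is not given, and equal cell numbers do not adjust for it.

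**Figure D4:**
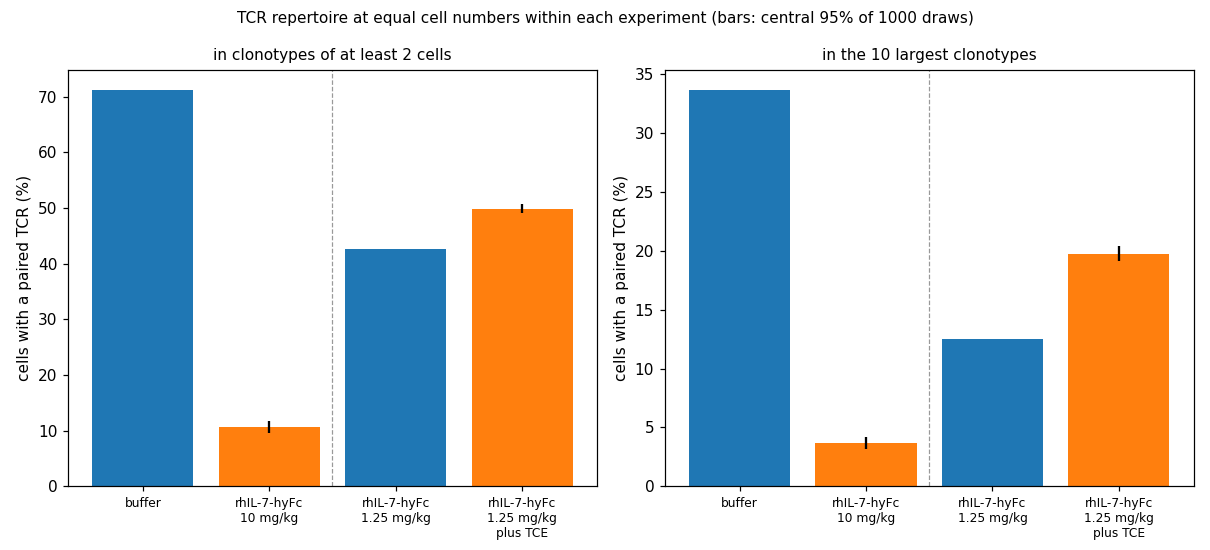
Share of cells with a paired TCR (vertical axis, percent) in clonotypes of at least 2 cells (left) and in the 10 largest clonotypes (right), by library, at equal cell numbers within each experiment; error bars are the central 95% of 1000 draws, and the library with fewer cells was used whole and has none. Clonotypes of at least 2 cells held 71.3% with buffer and 10.7% with rhIL-7-hyFc 10 mg/kg.

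Gzma also differed by clone size, counted in 4538 cells with rhIL-7-hyFc and 6336 with the combination, again without a test of that difference. Within clonotypes seen once (2602 and 3096 cells) it was at 195 CPM with rhIL-7-hyFc and 5813 CPM with the combination, and within clonotypes of at least 5 cells (1565 and 2737 cells) at 286 and 284 CPM. Effector differentiation genes had medians of 0.69 and −0.13 in these classes, G2 and M genes 0.53 and −0.18, and naive and memory genes −0.44 and 0.12. Mki67 was at 53.1 and 86.9 CPM within clonotypes seen once and at 91.8 and 77.2 CPM within expanded clonotypes. Exhaustion genes had a median of 0.47 within clonotypes seen once and 0.072 within expanded ones, and expanded cells exceeded cells seen once by 2.52 with rhIL-7-hyFc and 1.90 with the combination. Within cells with neither Pdcd1 nor Entpd1 (3345 and 2751 cells) the naive and memory median was −0.37 and the effector median 0.63, and within cells with either (3574 and 6992 cells) they were 0.15 and −0.019.

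Coordinates on GRCm38 for the genes that lead the text are as follows, all protein-coding. Gzma (ENSMUSG00000023132) lies on chromosome 13 from 113093825 to 113100981, minus strand, and Gzmk (ENSMUSG00000042385) on chromosome 13 from 113171608 to 113225908, minus strand. Gzmm (ENSMUSG00000054206) lies on chromosome 10 from 79689020 to 79695261, plus strand. Havcr2 (ENSMUSG00000020399) lies on chromosome 11 from 46454935 to 46481255, plus strand, and Tcf7 (ENSMUSG00000000782) on chromosome 11 from 52252371 to 52283014, minus strand.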

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

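Of the tests in this part, the share of barcodes with a beta chain and the ratio between libraries were chosen after the result was seen. Opposite directions by clone size led to the first group of results. The difference between clone size classes was not tested, each class comes from 1 library per group, and classes were set at unequal cell numbers. Lists were taken where both medians lay outside the central 95% of random lists.

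In the first comparison, cytokine and chemokine genes had medians of 0.13 within expanded clonotypes and −1.20 within clonotypes seen once, a gap of −1.33. Tissue residency genes had 0.13 and −0.98, a gap of −1.11. Transcription factors of CD8 T cells had 0.086 and −0.35, a gap of −0.43.

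In the second comparison, S phase genes had medians of −0.18 and 0.53, a gap of 0.71, and G2 and M genes −0.18 and 0.53, a gap of 0.71. Effector differentiation genes had −0.13 and 0.69, a gap of 0.82. Glycolysis genes had −0.25 and 0.27, a gap of 0.53. Cholesterol synthesis genes had −0.26 and 0.60, a gap of 0.85. Ribosomal protein genes had 0.065 and −0.20, a gap of −0.27.

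Barcodes with both T cell and myeloid RNA, which no comparison uses, made up 37.2% of the rhIL-7-hyFc library of experiment 2 despite a sort on TCRβ and CD8α. T marker UMIs per barcode were 4.86 times those in non-T barcodes of the library, but these classes had been split by their T marker level, so this decides nothing, and free T cell RNA in myeloid droplets cannot be told apart here. For an intact CD8 T cell beside a myeloid cell the values point apart: 29.9% of these barcodes (28.5 to 31.2) had a beta chain against 76.4% in the Cd8-high clusters, but they held 54.4 T marker UMIs per barcode against 42.2. By the beta chain share alone, as first set, this explanation was excluded; the reading was changed to weigh both values after they had been seen, so it stays open, and doublets may be part of the pattern. The share was 4.40 times that of the combination library, which with 1 library each cannot be told apart from a difference between libraries.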

How the results depend on the processing

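Among the alternatives, those without clusters that failed a version of the marker check, without multi-beta cells and top Scrublet scores, with the low-UMI clusters, and the share of cells under looser filters were chosen after seeing the data. Of the values under an alternative, 569 list medians stayed within their counting interval with the same sign, 463 moved beyond it with the same sign and 51 changed sign. For named genes these numbers were 1789, 1363 and 10. Of shares and repertoire values 123 stayed within, 143 moved beyond and 2 changed order. In the first comparison the naive and memory list stayed higher and the exhaustion and cytotoxicity lists lower under every alternative run. Leaving out doublet removal changed nothing, since no cell had been marked, and a clone size limit of 1% left no expanded cells with rhIL-7-hyFc 10 mg/kg, so no value. With 1 library per group, depth sets the counting intervals but no spread between mice could be had. The cause was not tested for the values in this part, except that scaling factors move all genes by nearly the same amount.

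In the first comparison the naive and memory median (1.22) was 0.75 under the UMI gate, 1.43 with edgeR TMM and 1.42 with DESeq2 size factors. It was 0.92 as a mean over cells, 1.03 after thinning, 0.39 with each clonotype once, 0.77 without Mki67 or Top2a cells, 1.33 at a CPM of at least 20 and 0.97 without cluster 7, which failed the marker check against all other cells. The exhaustion median (−1.82) was, in the same order of settings, −1.72, −1.62 and −1.62, then −2.05 as a mean over cells, −2.05 after thinning, −2.07 without Mki67 or Top2a cells, −1.92 at a CPM of at least 20, −1.93 with a pseudocount of 0.1, −1.97 without cluster 7, −1.28 without clusters 0, 10, 12 and 18, which failed against non-T clusters, and −1.01 without clusters 0, 3, 12 and 18, which failed against non-T and mixed clusters. The cytotoxicity median (−0.95) was −0.77 under the UMI gate, −0.74 with TMM and −0.74 with DESeq2 size factors. It was −0.97 as a mean over cells, −0.99 after thinning, −0.97 in cells with a paired TCR, −0.63 with each clonotype once, −1.09 without Mki67 or Top2a cells, −0.89 without cluster 7, −0.67 and −0.47 without these other sets of clusters, −0.99 without multi-beta cells and top Scrublet scores and −0.94 with the low-UMI clusters. Signs changed for B cell markers (−0.18, UMI gate), chemokine receptors, integrins and egress (−0.0014 as a mean over cells, −0.028 with each clonotype once, −0.024 without clusters 0, 3, 12 and 18), the IL-7 and STAT5 response (−0.091, each clonotype once), NK-type receptors (0.15, without Mki67 or Top2a cells) and cytokine receptors (−0.0043, CPM of at least 20). Il2 turned to −0.13 without clusters 0, 10, 12 and 18 and to −0.14 without clusters 0, 3, 12 and 18, and Mki67 to 0.046 without the latter. With TMM and with DESeq2 size factors signs changed for early genes of TCR signals (0.023 and 0.019), AP-1 and heat shock genes (0.047 and 0.042), oxidative phosphorylation (0.089 and 0.084), apoptosis and survival (0.031 and 0.026) and transcription factors of CD8 T cells (0.065 and 0.061). Oxidative phosphorylation was also at 0.0048 with each clonotype once.

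In the second comparison the naive and memory median (−0.38) changed sign to 0.043 under the UMI gate, which was not limited to the Cd8-high clusters. It was −0.44 with TMM, −0.44 with DESeq2 size factors, −0.45 as a mean over cells, −0.42 after thinning, −0.41 in cells with a paired TCR, −0.42 with no filter on low counts, −0.26 at a CPM of at least 20, −0.48 without cluster 6 (failing against all other cells), −0.21 without cluster 4 (against clusters outside the class) and −0.14 without cluster 1 (against non-T clusters). The exhaustion median (0.20) was 0.28 under the UMI gate, 0.14 with TMM, 0.14 with DESeq2 size factors, 0.33 as a mean over cells, 0.33 after thinning, 0.26 in cells with a paired TCR, 0.59 with each clonotype once, 0.34 without Mki67 or Top2a cells, 0.34 without cluster 6, 0.076 without cluster 4 and 0.053 without cluster 1. The cytotoxicity median (−0.11) changed sign to 0.016 after thinning, 0.043 with each clonotype once and 0.0020 without Mki67 or Top2a cells. It was −0.065 under the UMI gate, −0.17 with TMM, −0.17 with DESeq2 size factors, −0.0012 as a mean over cells, −0.055 in cells with a paired TCR, −0.051 without cluster 6, −0.17 without cluster 4, −0.18 without cluster 1 and −0.15 without multi-beta cells and top Scrublet scores.

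Other signs changed in the second comparison. Under the UMI gate these were chemokine receptors, integrins and egress (0.0091), ribosomal proteins (0.093), ribosome biogenesis and MYC targets (0.089), Ass1 (−0.52), Anxa1 (−0.66) and Il7r (0.043). With each clonotype once they were tissue residency (0.013), glycolysis (0.20), Tox (−0.39) and Ifng (0.094). Ribosome biogenesis and MYC targets stood at 0.0052 after thinning and 0.051 without cluster 6, and Il7r at 0.020 without cluster 6 and 0.0048 without cluster 1. Signs also changed for lists within the central 95% of random lists. NK-type receptors were at −0.043 as a mean over cells, −0.037 after thinning, −0.024 without Mki67 or Top2a cells, −0.22 with no filter on low counts and −0.091 without cluster 6. Apoptosis and survival genes were at −0.047 under the UMI gate, −0.031 as a mean over cells, −0.014 after thinning and −0.021 without cluster 6. CD3 and TCR signalling was at 0.27 under the UMI gate, 0.015 without Mki67 or Top2a cells, 0.0023 without multi-beta cells and top Scrublet scores, 0.028 without cluster 4 and 0.044 without cluster 1. B cell markers were at 0.025 under the UMI gate, 0.073 with each clonotype once, 0.13 without cluster 4 and 0.23 without cluster 1. CD4 T cell markers were at −0.085 with each clonotype once and −0.085 at a CPM of at least 20, early genes of TCR signals at 0.0019 without Mki67 or Top2a cells, and cholesterol synthesis at −0.013 without cluster 4. The order of clonotype numbers turned when all cells were used (2833 with rhIL-7-hyFc and 3409 with the combination), which follows from the larger number of cells.

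The share in Cd8-high clusters was 52.1% (buffer), 83.1% (rhIL-7-hyFc 10 mg/kg), 55.2% (rhIL-7-hyFc 1.25 mg/kg) and 85.0% (combination) with cells of at least 200 genes and under 20% mitochondrial UMIs, and 30.5% and 70.0% in experiment 2 at Leiden resolution 0.5. The share with neither Pdcd1 nor Entpd1 was, in the same order, 18.9%, 69.8%, 48.3% and 28.2% with all UMIs and 41.7%, 88.6%, 62.9% and 54.6% when at least 2 UMIs were needed. Under the UMI gate it was 30.7% with buffer and 46.4% with rhIL-7-hyFc 1.25 mg/kg. The share of cells in clonotypes of at least 2 cells was 62.2% (buffer) and 45.1% (rhIL-7-hyFc 1.25 mg/kg) over all barcodes, 44.7% (rhIL-7-hyFc 1.25 mg/kg) by beta CDR3 only and 12.2% (rhIL-7-hyFc 10 mg/kg) with all cells. With classes from thinned UMIs, the naive and memory median in cells with neither gene was 0.46 in the first comparison (0.30 before) and −0.41 in the second (−0.37 before). Exhaustion in expanded over singleton cells was 2.25 with rhIL-7-hyFc 1.25 mg/kg (2.52 before) and 2.11 with the combination (1.90 before) at a limit of 1% of paired cells, and 1.83 with the combination at a limit of 2 cells.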

Other observations

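The tests of depth and of the mix of clone sizes, including the value within clonotypes seen once, and the count of shared clonotypes were chosen after the result was seen.

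Among unnamed clusters with T cell RNA and low Cd8, which no comparison uses, NK receptor genes (Klra1, Klra7 and Klrb1c) led cluster 6 of experiment 1 and cluster 14 of experiment 2. A productive beta chain was found in 85.1% (buffer) and 90.2% (rhIL-7-hyFc 10 mg/kg) of the cells of these clusters in experiment 1, and in 64.7% (rhIL-7-hyFc 1.25 mg/kg) and 75.3% (combination) in experiment 2. By Pdcd1 and Entpd1 class, lists also took opposite signs in the second comparison. In cells with neither gene, S phase genes had a median of 0.62 and cholesterol synthesis genes of 0.49, against −0.057 and −0.12 in cells with a UMI of either. These classes rest on genes of the exhaustion list, were left out of the clone size results for that reason after their values had been seen, and their difference was not tested.

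Clonotypes identical in nucleotide sequence were found in more than 1 library. The libraries of experiment 1 shared 2 clonotypes (4 cells with buffer, 8 with rhIL-7-hyFc) and those of experiment 2 shared 5 (75 and 34 cells). Across experiments, buffer shared 2 with rhIL-7-hyFc 1.25 mg/kg (45 and 52 cells) and 1 with the combination, and rhIL-7-hyFc 10 mg/kg shared 4 and 2 with these libraries.

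The exhaustion list was lower in the rhIL-7-hyFc 10 mg/kg library. The median was −2.05 after thinning. Thinning does not alter the expected share of a gene among a cell's UMIs, so this value decides nothing on a difference in depth. RNA of non-T cells is argued against by a median of −1.95 over the 9 of 20 members that are low in non-T cells. Buffer profiles mixed in the clone size shares of the treated library gave −0.81, or 42.8% of the −1.89 observed in cells with a paired TCR, so another mix may account for part, and how large a part cannot be told apart here. The median of −1.90 within clonotypes seen once lies inside 1 class, so the mix of these classes cannot give it. Clone sizes were counted at unequal cell numbers, so clonotypes seen once can include cells of larger clones. How far this differs between the libraries was not tested. Treatment, a difference in depth, differences between mice and the library itself stay open, with 1 library per group.

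Gzma was higher in the combination library. Without cluster 6, which is mostly of that library, the log2 ratio was 2.96, against cluster 6 alone as the whole source. Cluster 11 (160 cells with rhIL-7-hyFc and 688 with the combination) also had Gzma among its top 10 genes and stayed in. Leaving out both clusters was not tried, so a different mix of clusters between the libraries was not tested as the source. Gzma UMIs per barcode in non-T cells differed by −3.18% of the difference in the Cd8-high clusters, against free Gzma RNA, though the combination library had 18 non-T cells. The added TCE and a batch difference between the libraries both stay open, as each group was 1 library.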
